A study of Mus musculus with 12 samples.

How the data were processed

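Gene expression was measured by RNA sequencing in bone marrow-derived macrophages, the macrophages that grow from cultured bone marrow, of C57BL/6 mice. The 12 libraries fall into 2 groups of 6, treated for 1 h with house dust mite (HDM) allergen or with vehicle. Groups and library numbers 1 to 6 were taken from the titles and the treatment field. The labels do not say whether libraries came from separate animals or cultures, so p-values measure the spread between these samples, which may be technical. If neighbouring numbers (1 and 2, 3 and 4, 5 and 6) share an animal, culture or batch, each group holds 3 independent samples in place of 6, and the standard errors and p-values given for n = 6 may be too small.

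Per the labels' protocols, RNA was purified on columns with DNase digestion and made into libraries with a stranded, poly(A)-selecting kit. The deposited values are raw counts per gene, not scaled, in 1 table of 50559 gene symbols and 12 columns, each matched to a library by its title. Per the submitters' processing notes, the tools were FastQC 0.12.1, Trim Galore 0.6.10, cutadapt 4.5, STAR 2.6.0c, featureCounts 2.0.6 and Subread, and the builds named were GRCm38 and mm39, with no role given to either. No coordinates are therefore printed. The strand setting of the counting, the annotation release and the read layout are not given in the sources used here, so overlapping and antisense genes cannot be told apart with certainty, and genes with near-identical copies can lose or share reads. All 643 members of the 27 gene lists below were found in the table by symbol, 15 of them under another name: Il36g as Il1f9, Akap2 as Pakap, and the 13 mitochondrially encoded genes in the style of COX1 for mt-Co1. Every line of the table names a gene.

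The test was edgeR's quasi-likelihood F test (edgeR 4.0.16, limma 3.58.1, R 4.3.3) on the counts as deposited, two-sided, with TMM factors, the filterByExpr filter at its default settings, and group as the only term. It left 13530 tested genes of the 27925 with at least 1 read. P-values were adjusted by the Benjamini-Hochberg method and a gene was called at an adjusted p under 0.05. Fold changes are HDM over vehicle. The standard error of a log2 fold change is its absolute value divided by the square root of F. Levels are CPM (counts per M reads) with TMM factors, as mean ± SD over 6 libraries.

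Gene lists were tested with camera on voom values with its preset correlation of 0.01, two-sided and adjusted over the 27 lists, and beside it with the correlation estimated per list and with fry, which asks whether a list's genes move on balance 1 way. For each list the members called over all tested genes are given beside those called with p adjusted over the list alone. The lists hold inflammatory cytokines, chemokines, immediate early transcription factors, the NF-kB pathway and its feedback, negative feedback of MAPK signalling and mRNA decay, the type I interferon response, alternative activation, calcineurin-NFAT targets, NFAT and calcineurin components, AKAP scaffolds and PKA subunits, store-operated calcium entry, the CREB and cAMP response, allergen-sensing receptors, heat shock and the unfolded protein response, NRF2 targets, glycolysis, sterol synthesis, proliferation, macrophage identity, ribosomal proteins, mitochondrially encoded genes, and markers of dendritic cells, neutrophils, lymphocytes, mast cells with basophils and eosinophils, stroma with endothelium, and erythroid cells with megakaryocytes. The list of MAPK signalling and mRNA decay also holds cytokine feedback genes (Cish and the Socs family) and Gadd45 genes. Of the members of all lists, 524 passed the filter. Genes named are the 15 largest rises and 10 largest falls among called genes with a mean of at least 1 CPM that lie on 1 side of the vehicle mean in all 6 HDM libraries, gene models without a descriptive symbol skipped, up to 4 members per list with the smallest p, and Akap5, Orai1, Stim1, Nfatc1, Rcan1, Tnf, Il6, Il1b, Cxcl2, Ccl3, Fos, Egr1, Nfkbia, Tlr4 and Clec4n in every case. A few more members are named where a count is small, chosen after their values were seen. Some genes that the rule picks are left out of the text, though the counts include them. The groups, lists, rule for named genes, tests and first set of alternatives were chosen before the data were examined.

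Both groups carry the numbers 1 to 6, so the deviations of log2 CPM from the group means were correlated across genes between the HDM and the vehicle library of each number. The 6 correlations were 0.467, 0.367, 0.387, 0.479, 0.624 and 0.672. All lie above the bound of 0.1 set in advance, so by that rule the numbers were taken to pair the samples, which rests on the data and not on a statement in the labels. The bound does not single out equal numbers: libraries numbered 1 and 2 against 3 and 4 correlated at 0.190 to 0.295, and 5 and 6 against 1 to 4 had a median of -0.47, so the split between these numbers shapes the correlations. The other number of the same neighbouring pair (1 and 2, 3 and 4, 5 and 6) correlated as well, with a median of 0.497, and only 2 of the 6 HDM libraries correlated best with the vehicle library of their own number. Results of a fit with the replicate number as a block are printed where they change a call or move a count by over 1.5 times.

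Counts were simulated for 13409 genes, 200 of them changed, with the library sizes of the HDM and vehicle libraries. Each gene had 1 starting mean per library number, shared by its HDM and vehicle library, and the spread of the block fit. Equal numbers were thus built in as true pairs, and differences between numbers fell equally on both treatments. The simulation could therefore not test that pairing, nor show false calls that arise without it. On these counts the test recovered 67.6%, 92.4% and 100% of changes of 0.5, 1 and 2 on the log2 scale, and called 0 unchanged genes (0 with voom too). With the block it recovered 95.6%, 100% and 100% and called 10 unchanged genes. Camera recovered 2 of 2 planted lists and called 0 of 20 lists of unchanged genes. The simulated noise was drawn for each gene separately and the unchanged lists held random genes. The simulation could therefore not show false calls of lists whose genes vary together. In the data the correlation estimated within a list reached 0.98, for proliferation. Within each group, a chi-square check of the counts found 0 of 30 pairs of libraries within sampling noise, so no library was treated as a copy of another. The closest pairs were neighbouring numbers: HDM 3 and 4 (2.26 per degree of freedom), vehicle 5 and 6 (2.91), HDM 5 and 6 (3.53), vehicle 3 and 4 (4.02) and vehicle 1 and 2 (6.67). All other pairs lay at 10.0 or above, among them the neighbours HDM 1 and 2 (19.6). A shared source of neighbouring numbers therefore stays possible.

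Library totals ran from 19.7 to 119.71 M counted reads (M, mega), so counting error is small except for genes under about 1 CPM. Intervals given for read counts are exact, at 95%, and cover counting error only. Alternatives were DESeq2 size factors, upper-quartile factors or total size in place of TMM, no filter or a stricter one, the robust setting, limma-voom, DESeq2 1.42.0, the block, library size as a covariate, both together, each library left out in turn, a stricter threshold, and the 20 most abundant and the mitochondrial genes left out. Others were added after seeing the data: a block of neighbouring numbers, numbers 1 to 4 only (with and without the block), numbers 5 and 6 only, and neighbouring numbers summed. Of the symbols, 48908 are in the RefSeq gene table of GRCm38, which was used for names only. Transcript lengths, GC content and shared sequence were taken from the GENCODE vM21 transcripts of that build.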

Results

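The data describe the transcripts of bone marrow-derived macrophages from C57BL/6 mice after 1 h with house dust mite (HDM) allergen, an extract that sets off airway allergy, or with vehicle. There were 6 libraries per treatment. Counted reads per library had a median of 41.11 M with HDM and 41.71 M with vehicle, from 19.7 M in the vehicle library numbered 5 to 119.71 M in the HDM library numbered 1. Mitochondrially encoded genes took 0.927% ± 0.207 of the counts with HDM and 0.804% ± 0.0991 with vehicle (SD, n = 6 each). The first principal component of log2 CPM held 42.2% of the variance and set the libraries numbered 5 and 6, of both treatments, apart from the other 8. The second held 23.6% and parted HDM (13.9 to 21.8) from vehicle (-23.7 to -13.6).

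**Figure D1:**
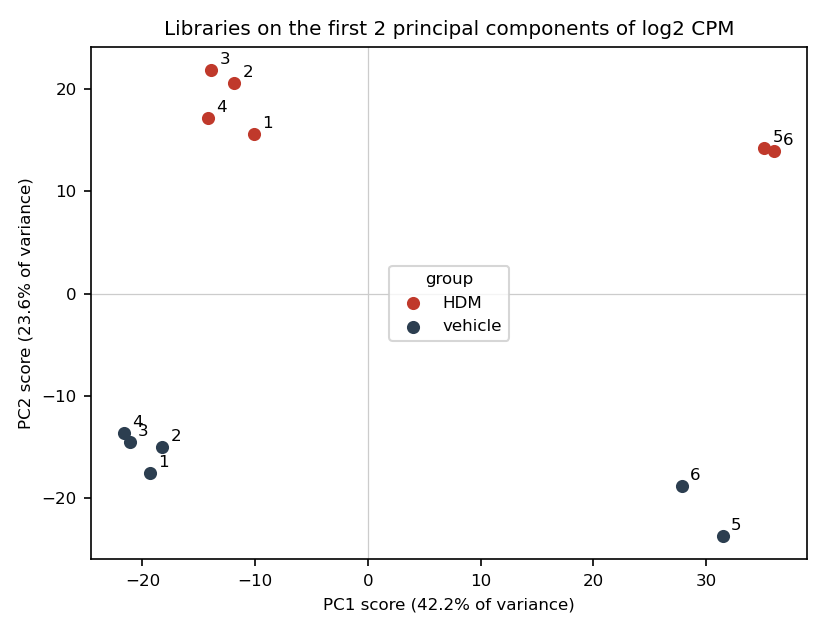
Score of each library on the first (x axis) and second (y axis) principal component of log2 CPM, without units. Points are libraries, coloured by treatment and marked with their number. The HDM libraries lie at 13.9 or above on the second component and the vehicle libraries at -13.6 or below, and numbers 5 and 6 lie at 27.8 or above on the first.

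The series compares HDM with vehicle to find the transcripts that the allergen changes, in a study of AKAP79/150, a scaffold that holds protein kinase A and the phosphatase calcineurin near their substrates. After 1 h, genes of secreted inflammatory mediators, early response genes and feedback inhibitors such as Nfkbia were among the largest rises. Cxcl2, a chemokine that draws neutrophils, rose from 9.93 ± 2.35 to 673 ± 134 CPM (SD, n = 6 each, log2 fold change 6.10 ± 0.19 SE, adjusted p = 1.64e-09). Tnf, which encodes a central inflammatory cytokine, rose from 12.03 ± 0.994 to 160 ± 32.8 CPM (log2 fold change 3.73 ± 0.13 SE, adjusted p = 1.95e-09), and Nfkbia, which encodes the inhibitor of NF-kB, rose from 44.8 ± 8.55 to 508 ± 61.6 CPM (3.50 ± 0.13, adjusted p = 3.25e-09). The median size of a log2 change was 0.476 among genes that rose and 0.359 among genes that fell. It was 0.206 and 0.203 among those called with the replicate number as a block. The quasi-likelihood test called 727 of 13530 tested genes, of which 393 rose and 334 fell. With upper-quartile factors the counts were 360 and 408 and with total size 347 and 413, so which direction is more frequent turns with the scaling. With TMM factors 382 of the rises and 320 of the falls held between the HDM and vehicle library of every number. Of the 727, 149 changed at least 2-fold, 120 up and 29 down. With the replicate number as a block the test called 1990 genes, 1069 up and 921 down, with 726 of the 727 among them, all in the same direction. Libraries numbered 5 and 6 alone gave 1139 genes, 526 of them among the 727. The other 8 gave 1076, with 624 among the 727. In each pair of neighbouring numbers (1 and 2, 3 and 4, 5 and 6) all 393 rises had a higher mean with HDM. All 334 falls had a lower mean there. The genes were called on these same libraries, so these counts and the 382 and 320 above describe the calls and do not test them.

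Among genes with a mean of at least 1 CPM the largest rise was that of Il6, which encodes a cytokine of the acute phase response. It had 2636 reads over the 6 HDM libraries and 6 over the vehicle libraries, a ratio per M reads of 358 (95% interval 164 to 977), and a log2 fold change of 8.48 ± 0.52 SE (adjusted p = 3.19e-07). Il1b followed at 7.32 ± 0.55 (adjusted p = 2.25e-06), then the neutrophil chemokines Cxcl1 at 6.52 ± 0.43 (adjusted p = 4.94e-07) and Cxcl2, and Ptgs2, which encodes the inducible cyclooxygenase, at 5.83 ± 0.44 (adjusted p = 2.27e-06). Below that mean, Areg, named after its value was seen, also rose strongly, from 0.0192 ± 0.0284 to 1.87 ± 1.66 CPM (adjusted p = 0.000656). Il10, which encodes an anti-inflammatory cytokine, rose by 4.41 ± 0.37 and Lif by 4.05 ± 0.53 (adjusted p = 5.68e-06 and 0.000372). Ier3, Cxcl10, Socs3, Tnfaip3 and Nr4a3 rose by 3.21 to 3.65, with adjusted p between 9.3e-08 and 0.00325. Apold1, at 19.4 ± 25.4 CPM with HDM and 1.05 ± 1.33 with vehicle, was the least certain of the 15 in the fit without the block (4.43 ± 1.14, adjusted p = 0.0398). In that fit its call was lost without HDM 5, HDM 6 or any of vehicle 1, vehicle 2, vehicle 3 and vehicle 4 (adjusted p 0.0811 to 0.0974). It was also lost with limma-voom (0.318) and with the robust setting (0.0502). With HDM it lay at 52.6 and 51.7 CPM in numbers 5 and 6 and at 2.75 to 3.13 in the others. It was higher with HDM in all 6 numbers, and with the block it was at 4.16 ± 0.08 (adjusted p = 6.03e-16).

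The largest falls were in genes of varied function. Nr1d1, a clock gene that encodes the repressor REV-ERB alpha, fell by 1.41 ± 0.23 on the log2 scale, from 24.0 ± 7.06 to 9.08 ± 2.53 CPM (adjusted p = 0.00217). Cxcr4, which encodes the receptor of the chemokine CXCL12, fell by 1.36 ± 0.20, from 158 ± 42.0 to 61.7 ± 16.97 CPM (adjusted p = 0.000849), and Bbc3, which encodes the pro-apoptotic protein PUMA, fell by 1.30 ± 0.08, from 21.7 ± 1.15 to 8.84 ± 1.16 CPM (adjusted p = 3.19e-07). The zinc finger genes Zkscan14, Zfp472 and Zfp87 fell by 1.21, 1.17 and 1.08, Frat1 and Frat2, whose products bind the kinase GSK3, by 1.16 and 1.04, and Rhov, a GTPase gene, by 1.14, with adjusted p between 8.45e-08 and 5.16e-05. H2-K2 fell by 1.26 ± 0.10 (adjusted p = 4.68e-06), but it belongs to the MHC class I family, whose near-identical members can share reads, so its value is uncertain.

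**Figure D2:**
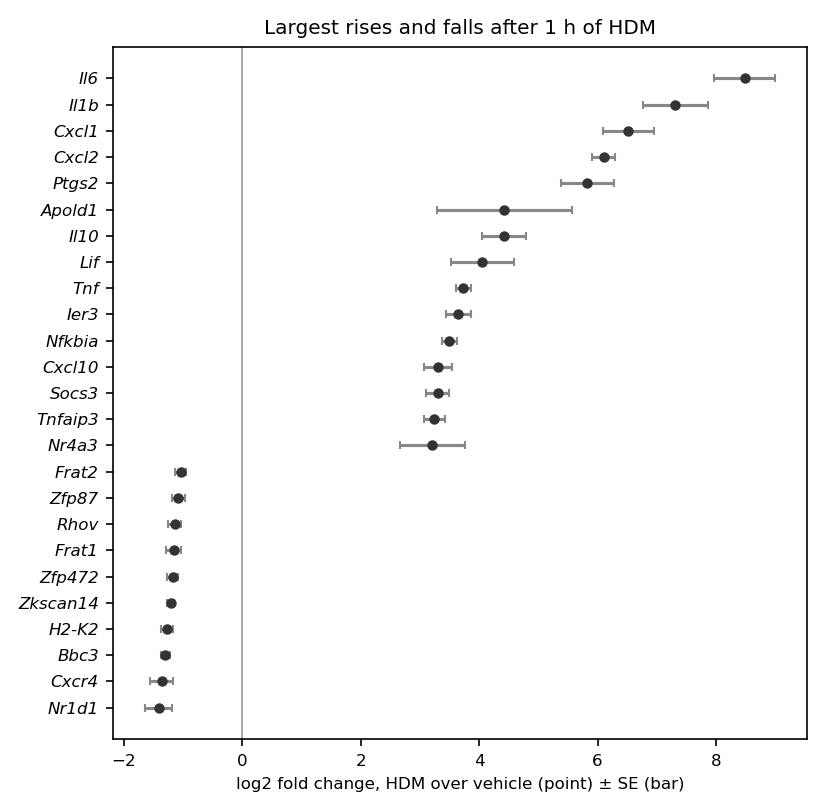
The 15 largest rises and 10 largest falls after 1 h of HDM. The x axis gives the log2 fold change of HDM over vehicle (6 libraries each), points are the estimates and bars ± 1 SE. Il6 is highest at 8.48, the Apold1 bar is the widest (SE 1.14) and the falls lie between -1.41 and -1.04.

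Secreted mediators rose as a group. Of 19 tested cytokines, 9 rose (Tnf, Il1b, Il6, Il10, Il27, Lif, Osm, Csf3 and Tnfsf9) and none fell (0 at an unadjusted p under 0.05, 0 with limma-voom, DESeq2 or the block). Adjusted over the list alone the count was 12, and with the block 14. Tnfsf9, the gene of a costimulatory ligand, went from 2.58 ± 0.466 to 23.7 ± 7.78 CPM (log2 fold change 3.19 ± 0.22 SE, adjusted p = 9.68e-07). Of 16 chemokines 9 rose, also 9 adjusted over the list alone. Beside Cxcl1, Cxcl2, Cxcl3 and Cxcl10 they were the CC chemokines Ccl2, Ccl3, Ccl4, Ccl7 and Ccl12, among them the monocyte attractant Ccl2, from 106 ± 8.72 to 328 ± 17.02 CPM (1.63 ± 0.06, adjusted p = 1.64e-09), Ccl7 at 1.65 ± 0.08 (adjusted p = 4.69e-08), Ccl4 at 1.73 ± 0.09 (adjusted p = 9.38e-08) and Ccl3 at 1.92 ± 0.18 (adjusted p = 1.26e-05). Camera called both lists up, with adjusted p = 7.62e-15 for cytokines and 6.2e-19 for chemokines. Both calls held with an estimated correlation (adjusted p = 0.00683 and 0.000179), as did those of 5 more lists described next, of 14 called in all.

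Immediate early genes, the transcription factors and regulators induced without new protein synthesis, were the most widely changed list. Of 26 tested members 21 rose, and adjusted over the list alone 21 rose and 1 fell (Klf10, named after its value was seen, at -0.27 ± 0.09 SE on the log2 scale, adjusted p = 0.107 over all genes, and 0.000168 with the block). Fos went from 98.8 ± 45.3 to 630 ± 64.4 CPM (log2 fold change 2.68 ± 0.25 SE, adjusted p = 1.79e-05), Klf6 from 340 ± 22.5 to 611 ± 26.5 (0.85 ± 0.05, adjusted p = 1.27e-07) and Myc from 10.9 ± 1.69 to 28.6 ± 1.41 (1.38 ± 0.09, adjusted p = 3.75e-07). Ier2 rose by 1.14 ± 0.07 (adjusted p = 1.62e-07) and Egr1 by 2.57 ± 0.47, from 0.815 ± 0.200 to 4.69 ± 3.58 CPM (adjusted p = 0.00518). Camera called the list up (adjusted p = 7.48e-36, and 0.00164 with an estimated correlation).

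The NF-kB list mixes genes of the pathway, its targets and its feedback inhibitors. Of its 29 members 13 rose, 17 adjusted over the list alone. The 13 include 5 genes of the IkB family (Nfkbia, Nfkbib, Nfkbid, Nfkbie and Nfkbiz), with Nfkbid at a log2 fold change of 2.49 ± 0.09 SE (adjusted p = 3.25e-09), and Tnfaip3, which encodes the deubiquitinase A20, from 83.7 ± 12.8 to 793 ± 213 CPM (3.25 ± 0.17, adjusted p = 9.3e-08). Cd83, an activation marker, rose by 1.68 ± 0.08 (adjusted p = 3.53e-08). The list of MAPK feedback and mRNA decay also holds cytokine feedback genes (Cish and the Socs family) and Gadd45 genes. Of its 27 tested members 16 rose and 1 fell, against 19 and 1 adjusted over the list alone. Zfp36, whose product tristetraprolin promotes the decay of cytokine mRNA, rose from 102 ± 22.1 to 633 ± 37.2 CPM (2.63 ± 0.13, adjusted p = 3.53e-08), Dusp5, the gene of an ERK phosphatase, from 20.3 ± 4.2 to 94.1 ± 14.5 (2.22 ± 0.14, adjusted p = 3.97e-07) and Trib1 from 29.3 ± 3.68 to 75.0 ± 2.48 (1.35 ± 0.07, adjusted p = 7.19e-08). The fall was that of Gadd45a, by 0.74 ± 0.14 (adjusted p = 0.00777), named after its value was seen, while its relative Gadd45b rose. Camera called both lists up, NF-kB with adjusted p = 6.67e-22 and MAPK with 8.28e-31, and both held with an estimated correlation (adjusted p = 0.000701 and 5.51e-05).

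**Figure D3:**
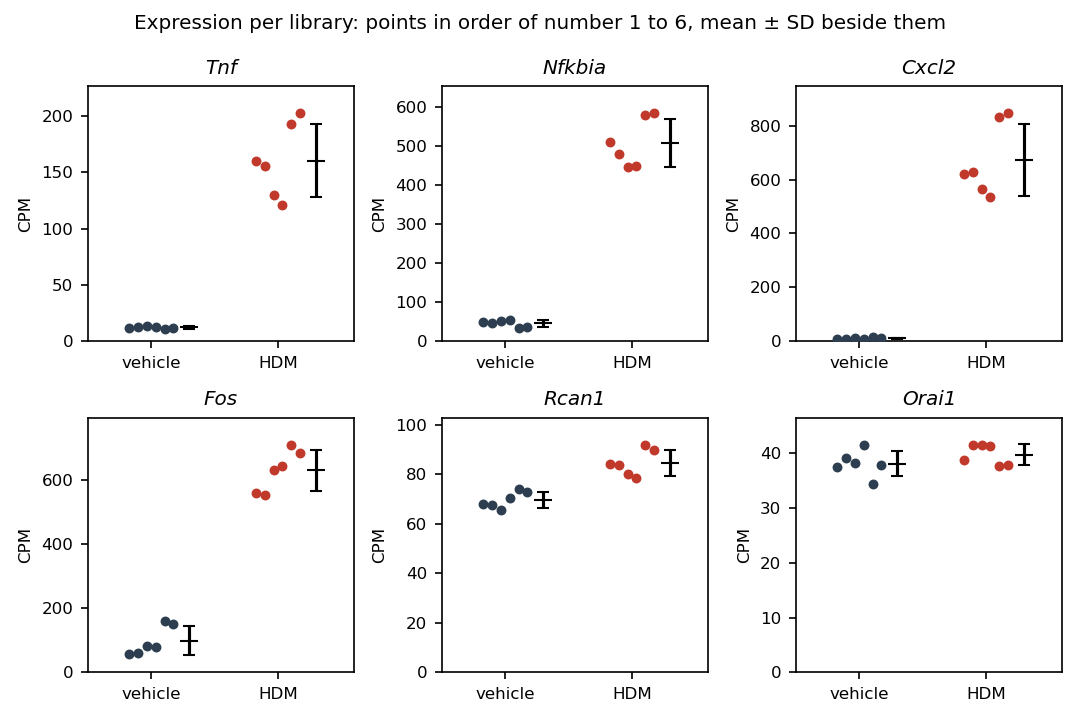
CPM in each library for 6 genes, with vehicle on the left and HDM on the right of each panel, points in the order of library numbers 1 to 6, and mean ± SD of 6 libraries beside them. Tnf lies at 10.9 to 13.7 CPM with vehicle and 121 to 203 with HDM, while Orai1 spans 34.4 to 41.5 with vehicle and 37.6 to 41.5 with HDM.

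AKAP79/150 anchors calcineurin and protein kinase A, so lists around these enzymes were examined. Genes listed as targets of calcineurin and its transcription factor NFAT rose in 12 of 16 cases, also 12 adjusted over the list alone, with the smallest p for Ccl2, Tnf, Socs3 and Myc (camera adjusted p = 8.28e-31, and 5.51e-05 with an estimated correlation). All 12 belong to another of the lists too, as do 15 of the 16. Of 25 genes of the CREB and cAMP response 14 rose, 16 adjusted over the list alone. Nr4a1, a nuclear receptor gene, rose from 16.9 ± 5.67 to 152 ± 29.3 CPM (log2 fold change 3.19 ± 0.21 SE, adjusted p = 4.78e-07) and Ptger4, the gene of a prostaglandin E receptor, from 25.9 ± 2.87 to 54.7 ± 3.34 (1.08 ± 0.07, adjusted p = 4.4e-07). Camera called the list up (adjusted p = 3.67e-23, and 0.00149 with an estimated correlation).

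Akap5 itself, the gene of AKAP79/150, was hardly detected: 16 reads over the 12 libraries, 11 with HDM and 5 with vehicle, or 0.0289 per M reads (exact 95% interval 0.0165 to 0.0469). Its counts ran from 0 to 4 per library. It did not pass the filter and was not tested. Its level was 0.0361 per M reads with HDM (0.018 to 0.0645) and 0.0201 with vehicle (0.00653 to 0.0469). A small change or a fall was out of reach at this depth. A rise as large as that of Csf3, from 0.0201 ± 0.0234 to 0.825 ± 0.246 CPM (adjusted p = 8.3e-06), was not seen. The kinase, phosphatase and calcium channel genes around it differed little. Rcan1, which encodes a calcineurin inhibitor that calcineurin induces, rose from 69.8 ± 3.20 to 84.7 ± 5.32 CPM (log2 fold change 0.28 ± 0.04 SE, adjusted p = 0.00176). With Nfatc3 (0.10 ± 0.02, adjusted p = 0.0315) it made 2 of 17 components of the NFAT and calcineurin pathway that rose, also 2 adjusted over the list alone, and Nfatc1 was at 0.03 ± 0.03 (adjusted p = 0.896), Rcan3 at -0.06 ± 0.04 (0.639) and Ppp3r1 at 0.06 ± 0.04 (0.698). Camera called that list up (adjusted p = 0.0248), not so with an estimated correlation (adjusted p = 0.332). The Nfatc3 call was lost without HDM 3, HDM 6, vehicle 1, vehicle 2 or vehicle 3 (adjusted p 0.0555 to 0.0794) and camera's call of the list without HDM 6, vehicle 1 or vehicle 2 (0.0541 to 0.0854). Fry did call this list higher (adjusted p = 0.0474, and 0.0193 with the block).

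Of 22 AKAP scaffolds and protein kinase A subunits, edgeR called 0, and 0 adjusted over the list alone, with 1 at an unadjusted p under 0.05, 0 with limma-voom, 1 with DESeq2 and 1 with the block. That gene was Akap10, at a log2 fold change of 0.09 ± 0.03 SE (adjusted p = 0.102, and 0.0302 with the block), followed by Akap11 at 0.05 ± 0.03 (0.505), Akap13 at 0.08 ± 0.05 (0.578) and Prkaca at 0.07 ± 0.04 (0.6). Camera's call of the list as higher (adjusted p = 0.0467) was lost with an estimated correlation (adjusted p = 0.11), and without HDM 1, HDM 3, HDM 4, HDM 6, vehicle 1, vehicle 2, vehicle 3 or vehicle 5 (0.0522 to 0.0908). Fry did call the list higher (adjusted p = 0.00858, and 0.00423 with the block), at a median log2 change of 0.04. Store-operated calcium entry refills calcium stores through ORAI channels gated by STIM sensors. Of its 27 genes, edgeR called 0 and 0 adjusted over the list alone, with 3 at an unadjusted p under 0.05, 1 with limma-voom, 2 with DESeq2 and 3 with the block. Orai1 was at 39.7 ± 1.86 CPM with HDM and 38.1 ± 2.29 with vehicle (0.06 ± 0.05, adjusted p = 0.737) and Stim1 at 76.6 ± 3.34 and 76.4 ± 3.68 (0.00 ± 0.04, adjusted p = 1). Atp2a2, the gene of the SERCA2 calcium pump, was at 0.10 ± 0.03 (adjusted p = 0.0557, and 0.00289 with the block), Stim2 at 0.10 ± 0.03 (0.0802, and 0.0349 with the block), Plcg1 at -0.10 ± 0.04 (0.259) and Letm1 at -0.05 ± 0.02 (0.495). The list was not called (adjusted p = 0.307), and its median change of 0.01 turned negative with upper-quartile factors and with total size.

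Allergen-sensing receptors and their adaptors changed in 4 of 34 cases, 2 up and 2 down, against 3 and 2 adjusted over the list alone and 6 and 4 with the block. Cd14, which encodes a co-receptor for lipopolysaccharide, rose from 507 ± 109 to 1189 ± 219 CPM (log2 fold change 1.23 ± 0.15 SE, adjusted p = 0.000162) and Tlr2 from 130 ± 8.28 to 276 ± 36.4 (1.09 ± 0.08, adjusted p = 1.79e-06). Ticam1 and Ticam2, the genes of the adaptors TRIF and TRAM, fell by 0.28 ± 0.05 (adjusted p = 0.00409) and by 0.22 ± 0.05 (adjusted p = 0.0323). The Ticam2 call was lost without HDM 1, HDM 2, HDM 3, HDM 4, vehicle 3, vehicle 4, vehicle 5 or vehicle 6 (0.0548 to 0.0817). Tlr4, the lipopolysaccharide receptor gene, was at 0.02 ± 0.06 (adjusted p = 1) and Clec4n, the gene of the mite-sensing lectin Dectin-2, at 0.05 ± 0.15 (adjusted p = 1). Camera did not call the list (adjusted p = 0.149), fry called it higher (0.0119), and its median of 0.02 turned negative with total size.

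Of 29 type I interferon response genes, 2 fell and none rose (0 at an unadjusted p under 0.05, 0 with limma-voom, DESeq2 or the block), also 2 adjusted over the list alone and 4 with the block. They were Stat2 and Irf9, genes of subunits of the interferon-activated factor ISGF3, which fell by 0.36 ± 0.07 (adjusted p = 0.00557) and by 0.21 ± 0.04 on the log2 scale (adjusted p = 0.0072). Oas3 was at -0.14 ± 0.06 SE (0.302, and 0.0376 with the block) and Xaf1 at -0.21 ± 0.09 (0.302). Camera called the list down (adjusted p = 0.000428), but with an estimated correlation it did not (adjusted p = 0.411). Markers of alternative activation, the macrophage state linked to type 2 immunity, rose in 2 of 16 cases, also 2 adjusted over the list alone. Both are shared with other lists: Cish, a gene of cytokine feedback (2.08 ± 0.22, adjusted p = 4.4e-05), and Klf4, an immediate early gene (1.14 ± 0.27, adjusted p = 0.0235). Arg1 was at 0.30 ± 0.10 (adjusted p = 0.133) and Irf4 at 0.45 ± 0.23 (0.429). Camera's call of the list as higher (adjusted p = 0.00843) was lost with an estimated correlation (adjusted p = 0.14) and with genes of 1 list only (0.37). Fry called the list higher too (adjusted p = 0.00858, and 0.00124 with the block). Klf4 was not called without HDM 5, HDM 6, vehicle 1, vehicle 2, vehicle 3 or vehicle 4 (0.0508 to 0.0604).

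In the lists of stress and metabolic genes most members were not called. The share called was still larger in each list than the 727 of 13530 over all tested genes, though on few genes. It was 4 of 24 in heat shock, 2 of 21 in NRF2, and 2 of 23 in glycolysis and in sterol synthesis. Of 24 genes of heat shock and the unfolded protein response, 1 rose and 3 fell, the same counts adjusted over the list alone, with 2 and 4 with the block. Chac1, Ddit3 and Atf4, which act in the integrated stress response, fell by 0.90 ± 0.19 (adjusted p = 0.0125), by 0.53 ± 0.14 (0.0459) and by 0.20 ± 0.05 (0.0423), and the chaperone gene Dnajb4 rose by 0.25 ± 0.06 (0.038). In the NRF2 list of 21, Osgin1 fell by 0.77 ± 0.15 (adjusted p = 0.00812) and Nfe2l2, the gene of NRF2, rose by 0.34 ± 0.08 (0.0218), with 2 up and 2 down adjusted over the list alone. With the block 3 rose and 3 fell, among them Txnrd1 (0.11 ± 0.03, adjusted p = 0.0874, and 0.00473 with the block) and Keap1 (-0.12 ± 0.04, 0.121, and 0.00853 with the block). In glycolysis, the hexokinase gene Hk2 rose by 0.24 ± 0.04 (adjusted p = 0.00313) and Pfkfb3 fell by 0.22 ± 0.04 (0.00773), 2 of 23. Adjusted over the list alone 2 rose and 1 fell, and with the block 3 and 1, one of them Slc2a1 (0.17 ± 0.05, adjusted p = 0.0549, and 0.00194 with the block), while Hif1a was at 0.07 ± 0.03 (0.323). In sterol synthesis 1 of 23 rose and 1 fell, the latter Mylip, which promotes decay of the LDL receptor, by 0.49 ± 0.08 (adjusted p = 0.00146). Adjusted over the list alone 2 rose and 1 fell, and with the block 2 and 5, with Hmgcs1 at 0.15 ± 0.05 (0.0779, and 0.00111 with the block) and Insig1 at -0.31 ± 0.11 (0.196, and 2.16e-06 with the block). Camera called none of these lists (adjusted p = 0.697, 0.974, 0.329 and 0.374), nor did it with the block, and fry with the block called heat shock and sterol synthesis down (adjusted p = 0.0454 and 0.00291). Fry's test for changes in either direction, without the block, called heat shock (adjusted p = 0.000927). It did not call NRF2, glycolysis or sterol synthesis (0.11, 0.0783 and 0.0903). The NRF2 median of 0.02 differs in sign from the mean (-0.01) and turned negative with upper-quartile factors and with total size, and the glycolysis median of 0.02 with total size.

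Several of these calls depended on single libraries. Dnajb4 was lost without HDM 1, HDM 2, HDM 3, HDM 4, HDM 6, vehicle 1, vehicle 2, vehicle 5 or vehicle 6 (adjusted p 0.0559 to 0.0873), and Nfe2l2 without vehicle 1, vehicle 2 or vehicle 3 (0.051 to 0.0557). Atf4 was lost without any library except HDM 3, HDM 4 and vehicle 5 (0.052 to 0.108), and Ddit3 without any except HDM 4 and vehicle 1 (0.0525 to 0.108).

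Genes that mark the macrophages themselves differed little between the treatments. Of 26 identity genes, 1 rose, Cd14, also 1 adjusted over the list alone. Csf1r, the receptor gene of the growth factor M-CSF, was at 1499 ± 50.7 CPM with HDM and 1522 ± 50.5 with vehicle (log2 fold change -0.02 ± 0.04 SE, adjusted p = 0.971), Trem2 at -0.04 ± 0.04 (0.889) and Laptm5 at -0.04 ± 0.04 (0.859). Camera did not call the list (adjusted p = 0.974), and its median (-0.02) and mean (0.02) differ in sign. Fry did not either (0.931), but with the block it called the list higher (0.0318). Of 25 proliferation genes edgeR called 0, and 0 adjusted over the list alone, with 0 at an unadjusted p under 0.05 and 0 with limma-voom or DESeq2. With the block 2 rose and 3 fell, by little. Mcm3 and Mcm6, helicase genes of DNA replication, were at -0.09 ± 0.12 and -0.09 ± 0.14 (adjusted p = 0.94 and 0.969, and 0.0285 and 0.0176 with the block), Hmgb2 at 0.14 ± 0.19 (0.943, and 0.00837 with the block) and Mki67 at 0.14 ± 0.24 (0.977). The list was not called (adjusted p = 0.826).

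Of 35 ribosomal protein genes edgeR called 0, and 0 adjusted over the list alone, with 2 at an unadjusted p under 0.05, 0 with limma-voom or DESeq2 and 1 with the block. That gene was Rpl10a at a log2 fold change of -0.11 ± 0.05 SE (adjusted p = 0.287, and 0.00315 with the block), beside Rpl14 at -0.09 ± 0.04 (0.313) and Rpl30 at -0.09 ± 0.05 (0.515). Camera called the list down (adjusted p = 0.0248), not so with an estimated correlation (adjusted p = 0.564) or without HDM 1, HDM 2, HDM 4, vehicle 1, vehicle 2 or vehicle 3 (0.0547 to 0.129). Of 8 tested mitochondrially encoded genes edgeR called 0, and 0 adjusted over the list alone, with 0 at an unadjusted p under 0.05 and 0 with limma-voom, DESeq2 or the block. COX1 was at 4793 ± 1079 CPM with HDM and 4018 ± 484 with vehicle (0.25 ± 0.13, adjusted p = 0.435), CYTB at 0.24 ± 0.13 (0.505), ND6 at 0.25 ± 0.16 (0.596) and ND3, uncertain at 31 to 157 reads per library, at 0.37 ± 0.25 (0.651). Camera called the list up (adjusted p = 0.0144), but not with an estimated correlation (adjusted p = 0.475), without HDM 2 (0.123) or without vehicle 2 (0.058).

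**Figure D4:**
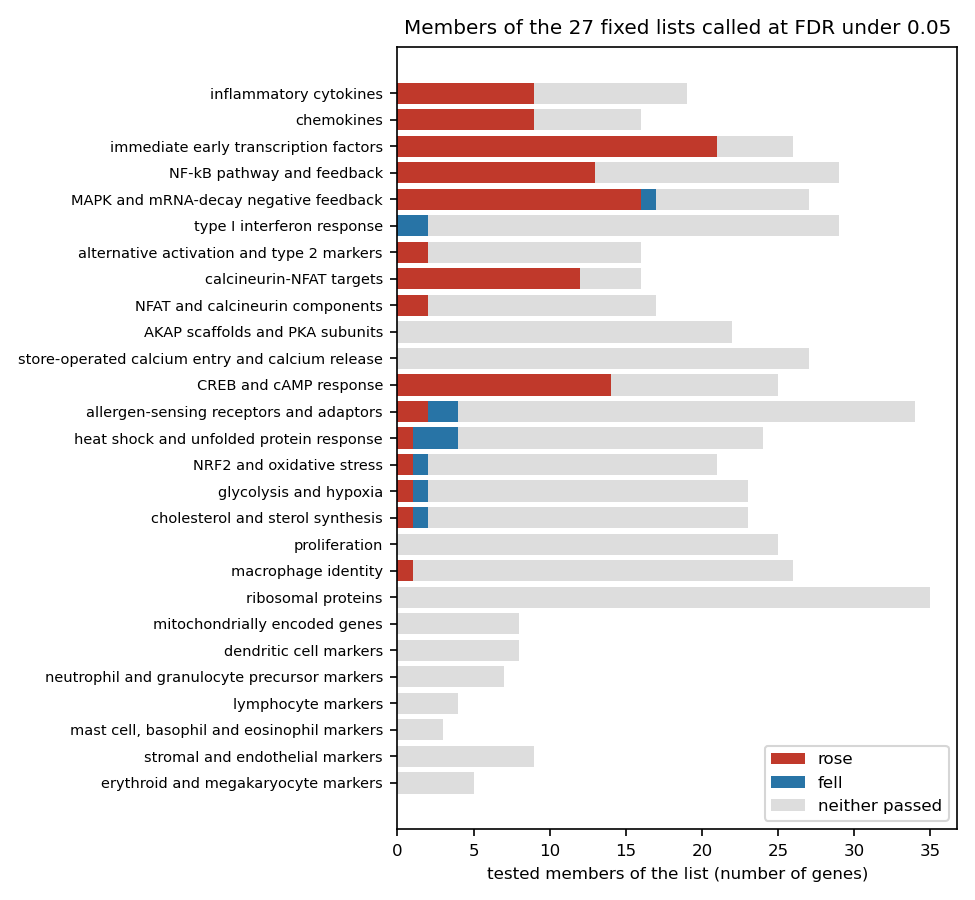
Tested members of each of the 27 lists (x axis, number of genes) that rose, fell or did neither in the quasi-likelihood test at an adjusted p under 0.05, with 6 libraries per treatment. Immediate early genes have the most rises, 21 of 26, and 11 lists, among them the 6 lists of markers of other cells, have no called member.

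Markers of other cells that a bone marrow culture could hold were examined too. In the list of stroma and endothelium no member was called. Bgn, a proteoglycan gene, was at 0.154 ± 0.109 CPM with HDM and 0.528 ± 0.278 with vehicle (log2 fold change -1.55 ± 0.46 SE, adjusted p = 0.0829, and 0.0125 with the block), Sparc at 0.236 ± 0.171 and 0.741 ± 0.340 (-1.40 ± 0.45, 0.11, and 0.00924 with the block), Postn at -1.09 ± 0.41 (0.194, and 0.02 with the block) and Acta2 at -0.33 ± 0.12 (0.207). Of the 9 tested members edgeR called 0, with 5 lower at an unadjusted p under 0.05, 4 lower adjusted over the list alone, 0 with limma-voom, 2 lower with DESeq2 and 5 with the block. Camera called the list down (adjusted p = 0.0287), a call that did not hold with an estimated correlation (adjusted p = 0.172), without vehicle 1 (0.067) or without vehicle 3 (0.0505). Fry called the stromal list lower too (adjusted p = 0.0309, and 0.0129 with the block). Camera called no other list of this kind, nor did it with the block. Fry with the block called dendritic cell markers (adjusted p = 0.0186, and 0.4 without the block) and mast cell, basophil and eosinophil markers (0.0125, and 0.429) higher and lymphocyte markers lower (0.0445, and 0.327). A small change in these cells with HDM is not excluded. For 8 dendritic cell, 7 neutrophil, 4 lymphocyte, 3 mast cell, basophil and eosinophil, and 5 erythroid and megakaryocyte markers, edgeR called 0 genes, 0 adjusted over the list alone, 0 at an unadjusted p under 0.05, and 0 with limma-voom, DESeq2 or the block, and camera gave adjusted p = 0.307, 0.307, 0.697, 0.307 and 0.954. In the order of these lists, Cd74 was at 12.03 ± 5.06 CPM with HDM and 10.9 ± 4.74 with vehicle (0.16 ± 0.30, adjusted p = 0.991), Csf3r at 33.6 ± 10.3 and 34.9 ± 11.3 (-0.07 ± 0.24, 1), Cd79b at 2.95 ± 1.52 and 3.26 ± 1.54 (-0.18 ± 0.41, 1), Siglecf at 4.83 ± 1.25 and 4.18 ± 1.13 (0.22 ± 0.20, 0.835) and Pf4 at 159 ± 42.3 and 153 ± 42.2 (0.06 ± 0.22, 1). The erythroid list's median of 0.01 and its camera direction differ in sign, and the median turned negative with upper-quartile factors and with total size.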

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

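The tests of the libraries numbered 5 and 6 in this part were chosen after the result was seen. In 256 groups of 6 values (library totals, mitochondrial shares and the 126 named genes, per treatment), 14 held a library whose gap to its nearest neighbour, relative to the whole range, passed Dixon's 95% critical value. Chance gives about 1 in 20, so 14 of 256 is close to its share.

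HDM 1 was sequenced to 119.71 M reads, against 19.8 to 46.4 in the other HDM libraries. In HDM 2 mitochondrial genes took 1.33% of counts, against 0.745 to 0.923%, with COX1 at 6878 CPM (others 3800 to 4728) and CYTB at 2028 CPM (others 1083 to 1347), and the mitochondrial list was not called without HDM 2 (adjusted p = 0.123) or without vehicle 2 (0.058). HDM 6 was highest for Klf6, at 661 CPM (others 581 to 609), and for Ppp3r1, at 158 CPM (others 138 to 144). HDM 3 was highest for Txnrd1, at 598 CPM (others 546 to 565), and HDM 4 lowest for Klrb1c, at 0.0723 CPM (others 0.342 to 0.474). Vehicle 5 was highest for the mitochondrial gene ND6, at 308 CPM (others 176 to 218), and lowest for Ppbp, at 0.207 CPM (others 0.756 to 1.04). Vehicle 3 was highest for 3 neutrophil genes, Ngp at 0.969 CPM (others 0 to 0.162), S100a9 at 1.13 (others 0.0158 to 0.162) and Lcn2 at 0.661 (others 0.0968 to 0.296). Vehicle 6 was highest for the stromal gene Postn, at 0.968 CPM (others 0.242 to 0.504).

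The 4 libraries numbered 5 and 6 stood apart from the other 8 in the level of many genes, in both treatments. With no overlap of ranges, 1848 of 13530 genes were higher and 2063 lower in the 4, 28.9% of genes. Chance gives 0.404% for a grouping fixed in advance, which this one was not, so the count describes the split and does not test it. Marco, a scavenger receptor gene of macrophages, lay at 5.30 to 6.58 CPM in the 4 and 51.5 to 79.0 in the 8, Cd5l at 37.8 to 47.0 and 205 to 330, and the matrix protease gene Mmp9 at 87.1 to 97.0 and 8.99 to 17.8. All 25 tested proliferation genes were lower in the 4, with Mki67 at 148 to 159 CPM against 234 to 364. Kit, a receptor gene of progenitors and mast cells, lay at 2.07 to 2.26 CPM against 0.145 to 0.399.

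Depth does not account for this split: with every library thinned to 19685273 reads the 4 still lay apart on the first component, which held 38.0% of the variance (42.2% before). A lower share of macrophage RNA does not account for the 14 genes at least 4-fold lower in the 4, since the 26 identity genes had a median log2 ratio of -0.14, from -1.77 to 0.79. Single identity genes did differ: 12 of the 26 were lower in all 4 than in any other library, and 7 were higher. RNA from other cells may contribute. All 4 libraries were higher for 62.5% of the dendritic list (5 of 8 tested markers) and 66.7% of the mast cell, basophil and eosinophil list (2 of 3, Kit and Gata2). Cd74 lay at 16.8 to 18.6 CPM against 7.56 to 10.2 and H2-Aa at 4.19 to 5.12 against 1.15 to 1.78. The neutrophil list was mixed: 42.9% were higher (3 of 7, among them Mmp9), but its median log2 ratio was -0.08. Its member Csf3r was lower in all 4, at 21.3 to 23.8 CPM against 34.1 to 48.9. Of the lymphocyte, stromal and erythroid lists, 0 of 4, 1 of 9 and 1 of 5 markers were higher in all 4, and 1, 2 and 2 lower. Of the 5 dendritic markers, 4 are MHC class II genes, which macrophages express too, the fifth is Cd24a, and the 3 other members overlapped, Xcr1 at 0.121 to 0.391 CPM against 0.260 to 0.562, Batf3 at 0.629 to 1.13 against 0.839 to 1.43 and Ciita, the gene of the activator of MHC class II genes, at 0.104 to 0.508 against 0.0792 to 0.307. Beyond the share of cells no biological explanation was tested, and a separate batch, culture or set of animals stays open because the labels give none.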

How the results depend on the processing

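The block of neighbouring numbers, the fits of numbers 1 to 4 or 5 and 6 only and the summed counts were chosen after seeing the data. The count of changed genes rose from 727 to 1990 with the replicate block, 1923 with the replicate block and library size, 2213 with a block of neighbouring numbers, 1741 for numbers 1 to 4 only with the replicate block, 1656 with neighbouring numbers summed and 1139 for numbers 5 and 6 only, and it fell to 383 at FDR under 0.01 and 149 at FDR under 0.05 and at least 2-fold. The block takes the difference between numbers out of the error: the biological coefficient of variation went from 0.129 to 0.0398. For the other rises the cause was not tested. Under the remaining settings the counts stayed within 1.5 times of 727, and with single libraries left out they ran from 561 (without vehicle 4) to 694 (142 to 153 for 2-fold changes). Camera called 7 lists in place of 14 with an estimated correlation and 10 (without vehicle 1) to 14 with single libraries left out. Of the 6 lists of other cells, the 1 called (stroma, lower) became 0 with no low-count filter, a block of neighbouring numbers, numbers 1 to 4 only, summed counts or an estimated correlation, and 0 to 1 with single libraries left out (0 without vehicle 1 or vehicle 3). The cause was not tested.

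For single lists, values are median log2 changes with the adjusted p of camera, or of fry where named. With an estimated correlation calls ended for type I interferon response (-0.15, 0.411), alternative activation (0.093, 0.14), NFAT and calcineurin components (0.031, 0.332), AKAP scaffolds (list: AKAP scaffolds and PKA subunits, 0.042, 0.11), ribosomal proteins (-0.036, 0.564), mitochondrial genes (0.23, 0.475) and stroma (list: stromal and endothelial markers, -0.81, 0.172). With fry they ended for type I interferon response (-0.15, 0.137), ribosomal proteins (-0.036, 0.226) and mitochondrial genes (0.23, 0.233), and allergen-sensing receptors gained one (0.019, 0.0119). With members of 1 list only they ended for alternative activation (0.056, 0.37), NFAT and calcineurin components (0.031, 0.13) and AKAP scaffolds (0.042, 0.0572), and calcineurin-NFAT targets, with 15 of 16 members in other lists, could not be tested so. With no filter they ended for AKAP scaffolds (0.038, 0.0621) and stroma (-0.51, 0.125), with a block of neighbouring numbers for AKAP scaffolds (0.043, 0.055), mitochondrial genes (0.22, 0.055) and stroma (-0.77, 0.134), with summed counts for AKAP scaffolds (0.037, 0.0681) and stroma (-0.39, 0.0817), and with numbers 1 to 4 only for stroma (-0.48, 0.151). With single libraries left out, medians ran from 0.020 to 0.043 for NFAT and calcineurin components (call lost without HDM 6, vehicle 1 or vehicle 2, 0.0541 to 0.0854), 0.036 to 0.057 for AKAP scaffolds (without HDM 1, 3, 4 or 6 or vehicle 1, 2, 3 or 5, 0.0522 to 0.0908), -0.050 to -0.023 for ribosomal proteins (without HDM 1, 2 or 4 or vehicle 1, 2 or 3, 0.0547 to 0.129), 0.098 to 0.29 for mitochondrial genes (without HDM 2, 0.123, or vehicle 2, 0.058) and -1.05 to -0.60 for stroma (without vehicle 1, 0.067, or vehicle 3, 0.0505). The cause was not tested.

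Of 126 named genes, 63 were called. Their 1827 values under alternatives kept direction and call in 1748 cases, lost the call in 79 and reversed in 0, and genes without a call gained 1 in 116 cases and changed sign with no call in 53. Of 22 genes named after their values were seen, Bhlhe40 reversed, at 0.21 in numbers 5 and 6 only (adjusted p = 0.000562). The replicate block changed no camera call of a list. It changed 6 fry calls and the calls of single genes whose values with the block stand in the report, and no other call of a gene whose change with HDM is given. Counting limits genes under about 1 CPM, such as Akap5, most.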

Other observations

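The class of zinc finger genes, the mitochondrial test and the comparison of numbers 5 and 6 were chosen after the result was seen. The split counts for lists with an estimated correlation and with the block were added after the count with the preset correlation was known.

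Most called genes lay outside the lists, as did most tested genes: the lists hold 524 tested members, some in more than 1 list, of 13530 tested genes. Of the 727 called genes 632 belong to no list, 309 up and 323 down. Of these, 48 changed at least 2-fold at a mean of 1 CPM or more (34 up, 14 down). The counts do not show that the response was stronger outside the lists. The genes named here were chosen after their values were seen. Kdm6b, which encodes a demethylase of the repressive histone mark H3K27me3, rose from 10.1 ± 1.74 to 63.3 ± 16.2 CPM (SD, n = 6 each, log2 fold change 2.65 ± 0.17 SE, edgeR adjusted p = 4.78e-07). Nfil3 rose from 21.0 ± 9.34 to 88.4 ± 20.3 CPM (2.09 ± 0.26, adjusted p = 0.000204) and Prdm1, the gene of BLIMP-1, from 10.98 ± 1.18 to 33.8 ± 4.13 (1.63 ± 0.09, adjusted p = 1.27e-07). Single genes that rose also include Trem1, an amplifier of inflammatory signalling (1.74 ± 0.19, adjusted p = 5.78e-05), Olr1, a receptor of oxidised LDL (2.26 ± 0.35, adjusted p = 0.00141), Ccrl2 (2.33 ± 0.34, adjusted p = 0.00104) and Cd69 (1.42 ± 0.16, adjusted p = 8.27e-05). Gem, a small GTPase gene, rose by 2.81 ± 0.36 (adjusted p = 0.000308), Phlda1 by 2.21 ± 0.09 (1.4e-08), Slc25a25, a calcium-regulated mitochondrial carrier gene, by 1.53 ± 0.05 (1.64e-09), and the polo-like kinase genes Plk3 and Plk2 by 1.36 ± 0.07 (7.19e-08) and 1.16 ± 0.14 (0.00016). Txnip, whose product inhibits thioredoxin, fell by 1.04 ± 0.11, from 224 ± 30.8 to 109 ± 18.1 CPM (adjusted p = 6.76e-05), and Klhl21, a ubiquitin ligase adaptor gene, by 1.00 ± 0.06 (2.25e-07). Every call in this paragraph held in all alternatives run on single genes.

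Other splits of the 12 libraries into 6 and 6 were tried, 100 of the 462 possible, the real one included. These counts treat the libraries as independent. As many changed genes as the real 727 came from 3 of them (highest other 1090), a share under 0.05. The 100 are a draw from the 462, so the share is itself uncertain and chance is not firmly excluded for this count. Both other splits with as many genes put all 4 libraries numbered 5 and 6 on 1 side, which points to the structure that these libraries make. However, 2 more splits that do so called 0 genes, and 97 of the 100 called 0 genes with edgeR. With neighbouring numbers as a block the real comparison gave 2213 genes. As many changes of at least 2-fold came from 1 of 100, the real one with 149 (highest other 93), so chance can be excluded only if the libraries are independent. For the 14 lists called with the preset correlation chance cannot be excluded, since 8 of 100 splits called as many, up to 16. For the 7 lists called with an estimated correlation it can, again only if the libraries are independent, since 1 of 100, the real one, reached that count (highest other 0). Of the 32 splits that part all 6 same-numbered pairs, fitted with the block, 1 gave as many genes, the real one with 1990 (highest other 0), so chance can be excluded if the 6 numbers are independent, and 2 gave as many lists (14, highest other 14), so for those it cannot. If neighbouring numbers share a source, 3 sets allow 4 such splits, too few for a share under 0.05, and no split was run with neighbouring numbers as a block. The 7 lists called with an estimated correlation (cytokines, chemokines, immediate early genes, NF-kB, MAPK and mRNA decay, calcineurin-NFAT targets and the CREB response) are therefore firmer than the other 7, though calcineurin-NFAT targets share 15 of 16 members with other lists and are not separate evidence.

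The log2 change with HDM differed between the libraries numbered 5 and 6 and the other 8 for 11 genes, by an interaction term in edgeR. The rise was smaller in numbers 5 and 6 for Ptgs2 (log2 fold change 5.24 ± 0.04 SE against 6.45 ± 0.14, adjusted p of the difference 0.0111), Dusp1 (2.16 against 3.12), Fos (2.17 against 3.09), Fosb (2.70 against 3.62) and Btg2 (0.29 against 1.16), each of which was higher in the vehicle libraries numbered 5 and 6, Fos at 156 ± 5.32 CPM against 70.2 ± 12.4. Bhlhe40 was also higher in the vehicle libraries numbered 5 and 6, at 86.8 ± 0.825 against 51.1 ± 4.24 CPM, but its change with HDM was more positive in these numbers. The rise was larger for Nfkbiz (2.88 ± 0.05 against 1.75 ± 0.05, adjusted p of the difference 4.04e-05), Nfkbia (4.07 against 3.24) and Gadd45b (1.84 against 1.13). Irf1 was at 0.60 against 0.00, Map3k8 at 0.34 against -0.12 and Bhlhe40 at 0.20 against -0.32. Of the 15 choices of 2 numbers 1 gave as many genes, numbers 5 and 6 with 11 (highest other 0), and 15 choices are too few for a share under 0.05.

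Zinc finger genes, the largest family of transcription factors, fell with HDM more often than other genes. The class was taken by symbol (Zfp, Zkscan, Zscan, Zbtb, Zik and Znf with a number). Every symbol that begins with Zfp36, not only the Zfp36 family, was left out and counted among the other genes. Of 395 zinc finger genes tested 69 fell and 3 rose (Zfp217, Zfp703 and Zfp438), 17.5% falls against 2.02% of other genes (odds ratio 10.3, 95% interval 7.59 to 13.8, Fisher's exact test p = 1.79e-39, over genes, which are not independent replicates). Their median log2 change was -0.11 against 0.00 for other genes, and it was negative under TMM, DESeq2, upper-quartile and total-size scaling. With the block 124 fell and 13 rose.

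Transcript length, GC content and expression level do not account for the falls: the lowest median of 10000 random lists matched on all 3 was -0.02, against -0.11 for the 393 zinc finger genes with a transcript (share of lists as low, the real one counted, 1e-04, the smallest the draws can give). A subset of the libraries does not either, since the median was lower than that of other genes in each pair of neighbouring numbers. It was -0.09 in 1 and 2, -0.09 in 3 and 4 and -0.14 in 5 and 6 (one-sided permutation p = 1e-05 in each, the smallest the draws can give). The permutation was over genes, which are not independent replicates, so this p does not measure the spread between libraries. A candidate explanation is that these transcripts turn over fast and are made less often within 1 h of HDM, which was not tested, as no data on decay or nascent RNA were used here.

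Of the 13 mitochondrially encoded genes, 6 had almost no reads in any library: COX2, COX3, ATP6, ATP8 and ND4L had at most 7, and ND3 31 to 157, where the lowest count of the other 7 was 4567. Reads shared with nuclear copies, which a counter that keeps only uniquely placed reads would drop, may account for 5 of the 6: over 90% of their 50-base words also occur in transcripts outside the mitochondrial genome, as for 0 of the 7 others (highest 62.2%, Fisher's exact test p = 0.00466, two-sided). ATP8 shares 0% and stays unexplained. Only annotated transcripts were searched, so a nuclear copy outside them would have been missed. Levels of these 6 genes, among them ND3 in the tested list, are therefore not to be read as expression, and the mitochondrial share rests on the other 7.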
